A study of Homo sapiens with 4 samples.

How the data were processed

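RNA sequencing libraries from cells labelled MHCC97-H, a human hepatocellular carcinoma cell line, were compared between 2 untreated libraries and 2 libraries made after 16 h with clofazimine, a riminophenazine antibiotic. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy column kit and polyadenylated RNA was made into libraries with an Illumina TruSeq RNA kit. The sample labels give the clofazimine dose as 40 uM and the description of the series gives 30 uM, and no source used here settles which was used. Groups were taken from the sample titles, and the file's control columns were matched to the titles that carry the word Wildtype and the same number.

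The authors deposited raw counts per gene for each library, per the file headers, as whole numbers for 58735 Ensembl gene identifiers. Per the submitters' processing notes, fastp and the human genome build GRCh38 were used. The aligner, the counting program, its strand setting and the annotation release were not given in the sources used here. The 58735 identifiers were the same set as the 58735 genes of GENCODE release 29, from which symbols, gene types and GRCh38 coordinates were taken. Reads of genes that overlap on opposite strands, and reads of near-identical copies, could have been assigned to either gene, because the counting rule is unknown. Among the genes the naming rule gave, DUSP1, RPS6, BBC3, SQSTM1, ACACA, FTH1, PTX3, NR1D1, FPR3, PPP1R10 and SCARA5 overlap a gene on the opposite strand.

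From the deposited counts, genes were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood test without a replicate term. Low counts were removed with filterByExpr at its defaults, a minimum count of 10 and a minimum total of 15, which left 16388 genes. Library sizes were scaled by TMM (trimmed mean of M values), with factors from 0.936 to 1.07. P-values were adjusted by the Benjamini-Hochberg method over the 16388 genes, and genes with an adjusted p under 0.05 were called. Levels are given as CPM, counts divided by the TMM-scaled library size and brought to 1 common scale, as mean ± SD with n = 2 libraries per group. The standard error of a log2 fold change is its size divided by the square root of the test's F value, and it was left out for genes with 0 counts in a whole group.

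Total counts per library lay between 13543437 and 16860578. At a floor of 3 counts, the largest mean that a count of 0 allows, levels down to 0.170 to 0.233 CPM could be seen, which covers counting error only because the reads carried no molecular identifiers. The biological coefficient of variation that edgeR estimated was 9.91%. The pipeline was tested on simulated counts for clofazimine against untreated over 16388 genes, of which 200 were changed. It called 46.3% of the genes changed 1.5-fold, 68.7% of those changed 2-fold and 92.4% of those changed 4-fold, and 6 of its 144 calls were false. The simulated changes were balanced up and down, and each gene had the dispersion of the fitted trend. Since 9811 genes were called in the data, these rates may not carry over to them. Within each group the replicates differed by more than counting noise, with a chi-square per degree of freedom of 5.81 for the untreated and 11.8 for the clofazimine libraries, so no library's counts were a copy of another's, which does not show that the libraries came from separate RNA.

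The gene lists, the design, the rule for named genes and all but 1 of the alternative settings were fixed before the data were examined. The 33 lists hold 612 entries and cover stress responses, metabolism, proliferation, cell death, cell identity, other cell types and RNA quality. Of these, 31 had at least 5 tested members and were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 31 lists. Calls were repeated with an estimated correlation and with fry, limma's rotation test. The rule named genes with an adjusted p under 0.05, a mean of at least 5 CPM, an approved-style symbol and both clofazimine libraries on the same side of both untreated libraries. It took the 6 highest and the 6 lowest fold changes, the 2 largest changes in the list's direction in each of the 8 lists with the smallest camera p, and the gene with the smallest adjusted p in each of the next 8 lists. The rule set lists of RNA quality and of other cell types to be given as counts only, and the text departs from it where it gives values for named members of those lists. The rule gave 32 genes, and all other genes in the text, those members included, were named after their values were seen. Some members of the lists are counted but not reported by name here.

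Alternatives were DESeq2 size factors, library totals without scaling, no filter, a filter of 1 CPM in 2 libraries, the DESeq2 1.42.0 Wald test, limma-voom, a replicate block and leaving out each library in turn. A correction for exon length and GC content, fitted with mgcv 1.9.3 as an offset, was added after the data were seen. Families and lists added after the data were seen were set against 10000 random lists of the same size, matched on mean expression in 20 bins. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. All 4 count columns were used.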

Results

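Gene expression was measured in cells labelled MHCC97-H, a line derived from human hepatocellular carcinoma, to see how 16 h with clofazimine altered transcription. Clofazimine is a riminophenazine antibiotic, and its dose is given as 40 uM in the sample labels and as 30 uM in the series description. The deposited counts cover 2 untreated libraries, with 16429147 and 16860578 counts, and 2 clofazimine libraries, with 13543437 and 16318759 counts. The untreated libraries held 25763 and 26091 genes with a count, and the clofazimine libraries 24082 and 24086. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

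In the clofazimine libraries, stress-response and inflammatory genes were higher, led by GDF15, a secreted stress cytokine, at 45.0-fold, and ATF3, a stress-induced transcription factor, at 37.8-fold. GDF15 rose from 52.9 ± 10.2 to 2380 ± 323 CPM and ATF3 from 13.6 ± 2.81 to 516 ± 42.3 CPM (TMM-scaled counts, mean ± SD, n = 2 libraries per group). Of the heat shock genes 12 of 15 were also higher, of the cytosolic ribosomal protein genes 30 of 30 and of the targets of NF-kB 16 of 19. All 13 protein-coding genes of the mitochondrial genome were lower, as were 13 of 24 genes of DNA replication and S phase, with 2 higher. CYP24A1, the enzyme that inactivates vitamin D, was 33.4-fold lower. With an estimated inter-gene correlation no adjusted p of a list was below 0.32 (camera), and for DNA replication and S phase the adjusted p was 0.46. That setting tests on the 2 residual degrees of freedom that 2 libraries per group leave, so few calls could be made with it.

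Of 16388 genes tested, 9811 changed (59.9%), with 4828 higher and 4983 lower in the clofazimine libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). With library totals alone in place of TMM, 3732 genes were higher and 6245 lower, so that the share of higher genes was 37.4% in place of 49.2%. That scaling shifted the median fold change by -0.17 on the log2 scale, and the changes given here are relative to the TMM scale. At least 2-fold changes were called in 4325 genes, 1726 higher and 2599 lower, and at least 4-fold changes in 533 higher and 871 lower genes. The 2 groups did not overlap for 13236 genes (80.8%), where chance alone gives 33.3%. Log2 CPM correlated across genes at 0.992 between the untreated and 0.987 between the clofazimine libraries, and at 0.923 to 0.927 between groups, with genes not being independent replicates.

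Fold changes were ranked among genes within the limits of the naming rule, a mean of at least 5 CPM included. Besides GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176) and ATF3 (ENSG00000162772, chromosome 1, 212565334 to 212620777), the highest belonged to 4 genes of different kinds. SNAI2 (ENSG00000019549, chromosome 8, 48917604 to 48921740), a transcription factor that represses epithelial genes, rose 29.2-fold from 4.29 ± 0.418 to 125 ± 1.59 CPM. PTX3 (ENSG00000163661, chromosome 3, 157436789 to 157443628), a secreted pattern-recognition protein, rose 28.6-fold from 0.995 ± 0.126 to 28.7 ± 1.08 CPM. GEM (ENSG00000164949, chromosome 8, 94249253 to 94262350), a small GTP-binding protein, rose 21.2-fold from 1.96 ± 0.292 to 41.8 ± 3.92 CPM. NR1D1 (ENSG00000126368, chromosome 17, 40092787 to 40100725), which encodes the circadian repressor REV-ERB alpha, rose 20.1-fold from 26.3 ± 1.90 to 529 ± 43.2 CPM. The log2 fold changes were 5.49 ± 0.19 (SE) for GDF15, 5.24 ± 0.17 for ATF3, 4.87 ± 0.15 for SNAI2, 4.84 ± 0.22 for PTX3, 4.41 ± 0.19 for GEM and 4.33 ± 0.15 for NR1D1. Their edgeR adjusted p-values ran from 1.71e-12 for SNAI2 to 4.43e-11 for PTX3. PTX3 and NR1D1 overlap VEPH1 and THRA on the opposite strand, and the strand setting of the counts is unknown.

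Within the limits of the naming rule, a mean of at least 5 CPM included, the lowest fold changes included CYP24A1 (ENSG00000019186, chromosome 20, 54153449 to 54173973). It fell from 81.9 ± 1.06 to 2.41 ± 0.767 CPM. FPR3 (ENSG00000187474, chromosome 19, 51795163 to 51826189), a formyl peptide receptor, was 29.9-fold lower at 14.03 ± 2.25 against 0.463 ± 0.00529 CPM. PPP1R10 (ENSG00000204569, chromosome 6, 30600400 to 30618612), a nuclear targeting subunit of protein phosphatase 1, was 19.1-fold lower at 82.3 ± 1.70 against 4.28 ± 0.442 CPM. SCARA5 (ENSG00000168079, chromosome 8, 27869882 to 27992727), a scavenger receptor that binds ferritin, was 17.1-fold lower at 23.4 ± 7.47 against 1.38 ± 0.467 CPM. The mitochondrial asparagine tRNA gene MT-TN (ENSG00000210135, mitochondrial genome, 5657 to 5729) was 20.8-fold lower, and the cysteine tRNA gene MT-TC (ENSG00000210140, 5761 to 5826) 16.2-fold lower. The libraries were made from polyadenylated RNA and the strand setting is unknown, so counts at these genes need not come from mature tRNAs. Log2 fold changes were -5.06 ± 0.19 (SE) for CYP24A1, -4.90 ± 0.31 for FPR3, -4.38 ± 0.25 for MT-TN, -4.26 ± 0.16 for PPP1R10, -4.10 ± 0.28 for SCARA5 and -4.02 ± 0.17 for MT-TC. FPR3, PPP1R10 and SCARA5 overlap other genes on the opposite strand, and for MRPS18B, the one over PPP1R10, the log2 fold change was 0.11 ± 0.14.

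**Figure D1:**
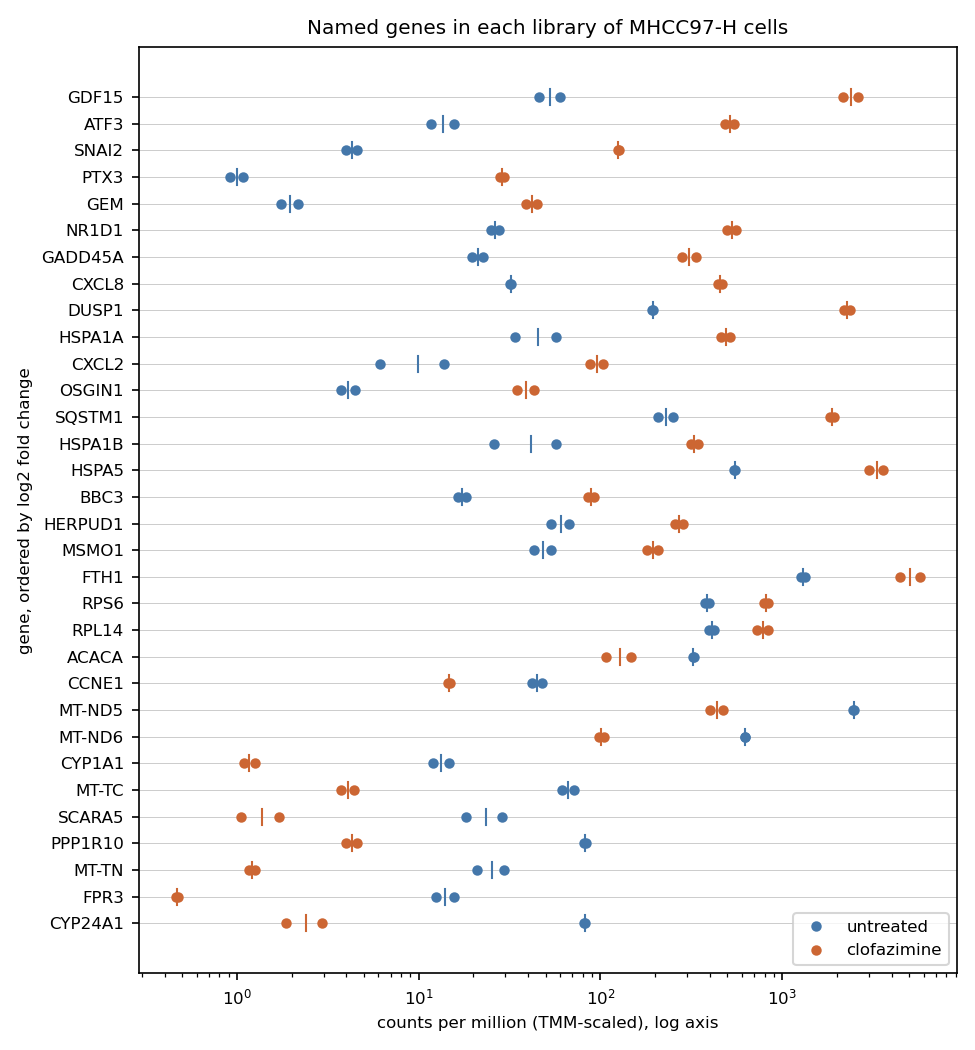
CPM (TMM-scaled counts on a log axis) of the 32 genes taken by the naming rule in each library, with points for the 2 untreated and 2 clofazimine libraries and a vertical line at each group's mean. For each gene both clofazimine libraries lie on the same side of both untreated libraries, from GDF15 (52.9 to 2380 CPM) at the top to CYP24A1 (81.9 to 2.41 CPM) at the bottom.

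Camera called 17 of the 31 lists at an adjusted p under 0.05, 13 upward and 4 downward. With an estimated inter-gene correlation camera called 0 lists after adjustment, with 2 at an unadjusted p under 0.05, and the lowest adjusted p was 0.32. That setting tests on the 2 residual degrees of freedom that 2 libraries per group leave. Few calls could be made with it, so a lost call says little for or against a list. Fry, which tests each list on its own and not against other genes, called 23 lists in 1 direction. Each list below was fixed before the data were examined.

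Immediate early genes, which respond to signals without new protein synthesis, had 12 of 17 members higher and 0 lower (13 adjusted over the list alone), at a median log2 fold change of 1.83. DUSP1, a phosphatase of MAP kinases, rose 11.8-fold from 194 ± 2.14 to 2287 ± 127 CPM, beside ATF3. Among the other members, JUN rose by a log2 fold change of 2.77, FOSB by 2.77 and NR4A1 by 2.52, while EGR1 (0.17) and IER2 (0.08) did not pass the test. For this list camera gave an adjusted p of 4.48e-16, and adjusted p = 0.32 with an estimated correlation.

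Targets of ATF4 and the integrated stress response had 19 of 25 members higher and 2 lower (22 changed adjusted over the list alone), at a median of 0.89. Beside GDF15 and ATF3, PPP1R15A, which helps to reverse the phosphorylation of eIF2 alpha, rose by 4.07, DDIT3, which encodes CHOP, by 3.82 and ASNS, the asparagine synthetase, by 3.07. The 2 members that fell were CHAC1, an enzyme that degrades glutathione, at -2.01, and VLDLR, a lipoprotein receptor, at -1.58. Camera's adjusted p for the list was 1.23e-14, and adjusted p = 0.45 with an estimated correlation. ATF3 counts in this list and among the immediate early genes.

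The list of the unfolded protein response of the endoplasmic reticulum had 10 of 19 members higher, 2 lower and 7 not called (12 changed adjusted over the list alone), at a median of 0.37 that was 0.20 under library totals. HSPA5, the main chaperone of that compartment, rose 6.04-fold from 549 ± 3.08 to 3313 ± 421 CPM. HERPUD1, a factor in the degradation of misfolded proteins, rose 4.49-fold from 60.4 ± 10.0 to 271 ± 20.2 CPM. CRELD2 (-0.56) and DNAJC3 (-0.37) fell, and the DNAJC3 call ended without untreated replicate 1 (-0.26), without clofazimine replicate 2 (-0.34), without a filter (-0.37) and with DESeq2 (-0.36), while it was at -0.61 with a correction for exon length and GC content. The CRELD2 call ended with that correction (-0.28). As a list it had a camera adjusted p of 5.62e-04, and adjusted p = 0.45 with an estimated correlation.

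Heat shock genes had 12 of 15 members higher and 0 lower (12 adjusted over the list alone), at a median of 1.08. HSPA1A rose 10.8-fold from 45.4 ± 16.0 to 489 ± 37.5 CPM and HSPA1B 7.94-fold from 41.5 ± 21.9 to 329 ± 22.6 CPM. These 2 genes encode near-identical HSP70 proteins, so the division of reads between them is uncertain. DNAJB1 and HSPH1, partners of HSP70, rose by 2.19 and 1.87. The camera adjusted p was 1.89e-09, and adjusted p = 0.45 with an estimated correlation. Under library totals 11 members were higher and 1 lower.

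Targets of NF-kB and inflammation had 16 of 19 members higher and 1 lower (17 changed adjusted over the list alone), at a median of 1.64. CXCL8, a neutrophil-attracting chemokine, rose 14.2-fold from 32.0 ± 0.137 to 455 ± 13.01 CPM, and CXCL2, a related chemokine, rose 9.59-fold from 9.96 ± 5.44 to 95.5 ± 11.1 CPM. The cytokine genes IL1B and IL6 rose by 3.38 and 2.81. CCL2, a chemokine for monocytes, fell by 2.99 on the log2 scale. For this list camera gave an adjusted p of 4.23e-12, and adjusted p = 0.45 with an estimated correlation. Interferon-stimulated genes divided, with 8 of 19 higher and 6 lower (15 changed adjusted over the list alone), among them ISG15 at 2.35 and IFI27 at -2.07. That list was not called (camera adjusted p 0.65), and its median of -0.16 and mean of 0.03 differ in sign. Under library totals 5 members were higher and 9 lower at a median of -0.32, and the median was -0.07 without clofazimine replicate 1.

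The mitochondrial genome has 13 protein-coding genes for subunits of the respiratory chain and ATP synthase. Of these 13 of 13 were lower (13 adjusted over the list alone), at a median of -0.79 that was -1.65 with the length and GC correction. MT-ATP8 overlaps MT-ATP6 and MT-ND4L overlaps MT-ND4, so the counts of these genes need not come from separate mRNAs. MT-ND6, the mRNA encoded on the light strand, was 6.17-fold lower at 625 ± 2.37 against 101 ± 5.19 CPM, and MT-ND5 was 5.67-fold lower at 2471 ± 29.1 against 436 ± 47.8 CPM. MT-ND6 (from 14149) adjoins MT-ND5 (to 14148) on the opposite strand. Since the strand setting is unknown, counts at MT-ND6 may include reads of heavy-strand RNA. The smallest drops were in MT-ATP6 (-0.44 ± 0.14, SE) and MT-ND4 (-0.46 ± 0.14), whose calls ended without untreated replicate 2 (-0.42 for each). The mitochondrial ribosomal RNA genes MT-RNR1 and MT-RNR2 were at 0.35 ± 0.14 and 0.36 ± 0.15. Their calls ended without untreated replicate 1 (0.25 and 0.35) or untreated replicate 2 (0.43 and 0.37), that of MT-RNR1 also without clofazimine replicate 2 (0.26) and without a filter (0.35), and both ended under library totals (0.18 and 0.20) and with the length and GC correction (-0.06 and 0.02). Mitochondrial genes held 3.69% and 3.75% of the counts in the untreated and 2.06% and 2.13% in the clofazimine libraries. For the 13 protein-coding genes the camera adjusted p was 9.06e-10, and adjusted p = 0.32 with an estimated correlation. Nuclear genes of the respiratory chain had 14 of 28 members higher and 3 lower (17 changed adjusted over the list alone), with SDHB at 0.85 and SDHA at -0.68, and 11 higher and 5 lower under library totals. They were not called as a list (camera adjusted p 0.078), but were without untreated replicate 2 (0.033) and without clofazimine replicate 1 (0.013), over a range of adjusted p from 0.013 to 0.77 across settings.

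**Figure D2:**
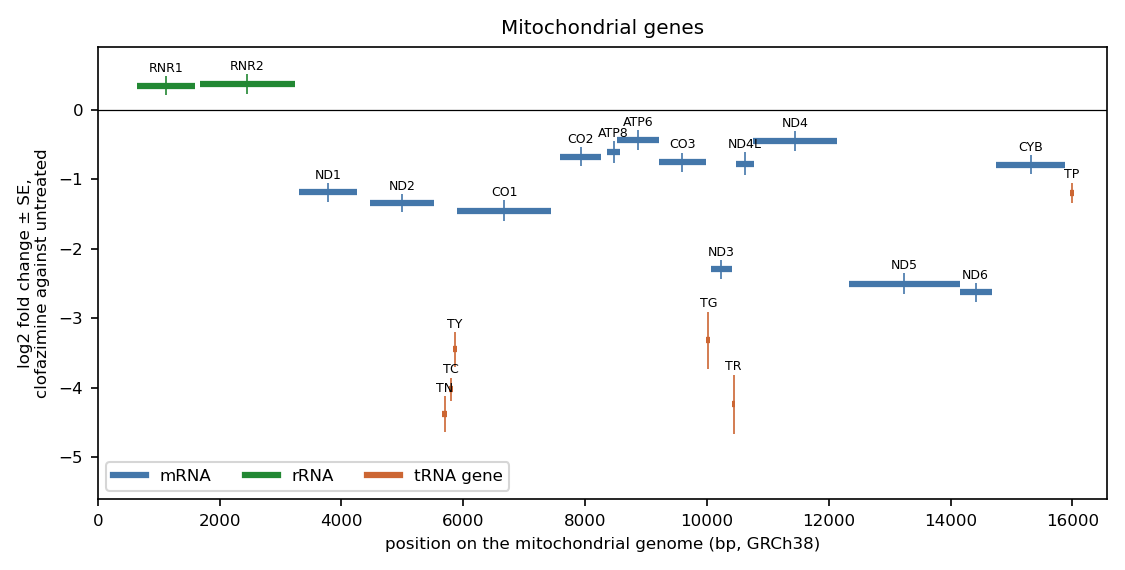
Log2 fold change of clofazimine against untreated (vertical bars are ± SE, n = 2 libraries per group) against position in base pairs on the mitochondrial genome, with horizontal segments spanning each gene and tRNA genes shown from 5 CPM in untreated cells. Counts at tRNA genes need not come from mature tRNAs. The 13 protein-coding genes lie between -0.44 and -2.63, and the tRNA genes shown between -1.19 (MT-TP) and -4.38 (MT-TN), with MT-TC at -4.02. The 2 ribosomal RNA genes lie at 0.35 and 0.36, calls that ended under library totals and with the length and GC correction (-0.06 and 0.02).

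Cytosolic ribosomal protein genes had 30 of 30 members higher (30 adjusted over the list alone), at a median of 0.77. RPS6 rose 2.12-fold from 385 ± 12.1 to 816 ± 24.5 CPM and RPL14 1.91-fold from 411 ± 18.6 to 783 ± 74.8 CPM. Under library totals 27 were higher and 0 lower, at a median of 0.60. Camera's adjusted p for the list was 1.85e-07, and adjusted p = 0.51 with an estimated correlation. Beside this group, the list of nuclear and small noncoding RNAs kept as a sign of RNA quality had 5 of 5 members higher, among them GAS5 at 1.98, SNHG1 at 1.63 and MALAT1 at 0.96 (5 adjusted over the list alone, camera adjusted p 0.0016, and adjusted p = 0.45 with an estimated correlation). Replication-dependent histone genes, the other sign of RNA quality, had 2 of 12 higher and 4 lower (6 changed adjusted over the list alone, camera adjusted p 0.98), with a median of 0.28 and a mean of -0.09 that differ in sign. That median was 0.11 under library totals, 0.07 with the length and GC correction and 0.09 without clofazimine replicate 2. Across 12993 genes, longer exon length went with lower fold changes (Spearman rho -0.15, across genes), and the 2 clofazimine libraries differed from each other by a length trend of -0.35.

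Antioxidant targets of NRF2 had 12 of 21 members higher and 3 lower (15 changed adjusted over the list alone), at a median of 0.61. OSGIN1, an oxidative stress-induced growth inhibitor, rose 9.56-fold from 4.09 ± 0.505 to 39.1 ± 5.96 CPM. FTH1, the ferritin heavy chain, rose 3.90-fold from 1304 ± 49.8 to 5078 ± 909 CPM, and HMOX1, heme oxygenase 1, rose by 1.38. The members that fell were the aldo-keto reductases AKR1B10 (-3.52) and AKR1C1 (-1.20) and the exporter ABCC2 (-1.17). As a list it had a camera adjusted p of 5.83e-04, and adjusted p = 0.46 with an estimated correlation. FTH1 overlaps BEST1 on the opposite strand.

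FTH1 also led the list of ferroptosis regulators and iron handling, with 9 of 18 members higher and 3 lower (14 changed adjusted over the list alone), at a median of 0.35 that was 0.19 under library totals and 0.15 with the length and GC correction. The light chain FTL and the polyamine acetyltransferase SAT1 rose by 1.61 and 1.49, and CHAC1 (-2.01), the metalloreductase STEAP3 (-0.86) and LPCAT3 (-0.58), which remodels phospholipids, fell. LPCAT3 was at -0.38 without clofazimine replicate 2. The list's camera adjusted p was 0.037, and adjusted p = 0.45 with an estimated correlation. The call ended without untreated replicate 1 (0.065), without untreated replicate 2 (0.10, at a median of 0.21) and under library totals (0.056, with 7 higher and 5 lower), over a range from 0.010 to 0.45 across the camera settings. Metallothioneins and metal response genes had 4 of 6 higher, with SLC30A1, a zinc exporter, at 1.26 and MT2A at 0.95, and SLC39A10, a zinc importer, lower at -0.65 (5 changed adjusted over the list alone, camera adjusted p 0.17).

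Regulators of apoptosis had 13 of 22 members higher and 2 lower (16 changed adjusted over the list alone), at a median of 0.45 that was 0.29 under library totals. BBC3, which encodes the pro-apoptotic protein PUMA, rose 5.11-fold from 17.4 ± 1.26 to 88.8 ± 4.72 CPM. PMAIP1, which encodes the pro-apoptotic NOXA, rose by 1.93, and the anti-apoptotic genes BIRC3 and BCL2 rose by 2.57 and 0.89. The pro-apoptotic genes BMF (-2.25) and APAF1 (-1.10) fell. The camera adjusted p was 0.0012, and adjusted p = 0.45 with an estimated correlation.

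Targets of p53 moved both ways, with 10 of 20 higher and 7 lower (18 changed adjusted over the list alone), and 8 each way at a median of 0.03 under library totals. GADD45A, a growth arrest gene, rose 14.6-fold from 21.1 ± 2.09 to 308 ± 38.7 CPM and CDKN1A, which encodes the cell cycle inhibitor p21, by 1.77. XPC and DDB2, genes of nucleotide excision repair, fell by 0.64 and 0.50 on the log2 scale. For this list camera gave an adjusted p of 0.0052 upward, and adjusted p = 0.45 with an estimated correlation. The median of 0.19 was 0.13 without untreated replicate 1, 0.30 without untreated replicate 2, 0.32 without clofazimine replicate 1 and 0.05 without clofazimine replicate 2.

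Genes of DNA replication and S phase had 13 of 24 members lower and 2 higher (17 changed adjusted over the list alone), at a median of -0.36 that was -0.18 with the length and GC correction. CCNE1, which encodes cyclin E1, was 3.06-fold lower at 44.9 ± 3.82 against 14.7 ± 0.198 CPM. UHRF1, CCNE2 and the sliding clamp PCNA fell by 1.32, 1.31 and 0.82 on the log2 scale. CDT1 (0.53) and POLE2 (0.42) rose, and the POLE2 call ended without untreated replicate 1 (0.38), untreated replicate 2 (0.44) or clofazimine replicate 1 (0.38), under library totals (0.25) and with the length and GC correction (0.26). Camera's adjusted p for the list was 0.020, and adjusted p = 0.46 with an estimated correlation. Mitosis genes divided, with 9 of 22 higher and 5 lower (14 changed adjusted over the list alone, camera adjusted p 0.46). UBE2C and TTK rose by 1.30 and 1.26, and PLK1 fell by 0.79 on the log2 scale. Under library totals 6 members were higher and 8 lower, and the list's median of 0.16 turned to -0.01, while it was -0.03 with the length and GC correction and 0.09 without untreated replicate 2.

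Genes of cholesterol synthesis and uptake had 13 of 24 members higher and 5 lower (18 changed adjusted over the list alone), at a median of 0.48 that was 0.31 under library totals. MSMO1, a sterol demethylation enzyme, rose 4.01-fold from 48.3 ± 7.53 to 194 ± 18.8 CPM, and HMGCS1, an early enzyme of the pathway, rose by a log2 fold change of 1.68. Among the members that fell were PMVK (-0.95), FDPS (-0.68) and SREBF2 (-0.41). The SREBF2 call ended without untreated replicate 2 (-0.31), without clofazimine replicate 2 (-0.29), without a filter (-0.41) and with the length and GC correction (-0.01). The list's camera adjusted p was 0.0094, and adjusted p = 0.51 with an estimated correlation. That call also ended without untreated replicate 1 (0.055, at a median of 0.40), over a range from 0.0022 to 0.51 across the camera settings.

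Fatty acid synthesis genes had 8 of 14 members lower and 3 higher (11 changed adjusted over the list alone), at a median of -0.42 that was -0.16 with the length and GC correction. ACACA, acetyl-CoA carboxylase, was 2.54-fold lower at 325 ± 3.23 against 128 ± 28.2 CPM, ELOVL6 and FASN fell by 1.22 and 0.77 on the log2 scale, and ACSS2 rose by 0.60. The list was not called (camera adjusted p 0.078), but was without clofazimine replicate 1 (0.026) and under library totals (0.046, with 1 higher and 9 lower), over a range from 0.026 to 0.52. Genes of fatty acid oxidation and PPAR targets had 4 of 17 higher and 6 lower (10 changed adjusted over the list alone, camera adjusted p 0.62), and 2 higher and 8 lower under library totals. The coactivator PPARGC1A and the lipid droplet gene PLIN2 rose by 1.92 and 1.89, and CPT2, a carnitine transferase, fell by 2.71 on the log2 scale.

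Autophagy genes had 9 of 20 members higher, 3 lower and 8 not called (12 changed adjusted over the list alone), at a median of 0.27 that was 0.10 under library totals, 0.57 with the length and GC correction and 0.44 without clofazimine replicate 2. SQSTM1, the cargo receptor p62, rose 8.28-fold from 228 ± 30.2 to 1889 ± 70.9 CPM, and MAP1LC3B and GABARAP, which encode autophagosome proteins, rose by 1.20 each. TP53INP1 (-1.15), TP53INP2 (-0.70) and ATG9A (-0.44) fell. The TP53INP1 call ended without untreated replicate 2 (-0.84), and the ATG9A call ended without it (-0.34) and without clofazimine replicate 2 (-0.16), without a filter (-0.44), with DESeq2 (-0.42) and with the length and GC correction (-0.14), while ATG9A was at -0.78 without clofazimine replicate 1. As a list it had a camera adjusted p of 0.0094, and adjusted p = 0.45 with an estimated correlation. Lysosome genes had 11 of 26 higher and 5 lower (16 changed adjusted over the list alone), with the sialidase NEU1 at 1.30 and the protease CTSB at -0.87. They were not called (camera adjusted p 0.0998), but were with the length and GC correction (0.016), without untreated replicate 2 (0.045) and without clofazimine replicate 1 (0.042), over a range from 0.016 to 0.74. Their median of 0.22 was 0.38 with the correction and 0.06 under library totals, and it was 0.12 without untreated replicate 1 and 0.15 without clofazimine replicate 2.

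Xenobiotic metabolism genes had 6 of 9 members lower and 1 higher (7 changed adjusted over the list alone), at a median of -0.61. CYP1A1, a classic target of the aryl hydrocarbon receptor, was 11.3-fold lower at 13.3 ± 1.81 against 1.17 ± 0.111 CPM, and ALDH3A1 and the receptor's repressor AHRR fell by 1.67 and 1.53 on the log2 scale. TIPARP, another target of the receptor, rose by 0.64. The camera adjusted p was 0.022, and adjusted p = 0.46 with an estimated correlation. The call ended without clofazimine replicate 2 (0.057, at a median of -0.60), over a range from 0.014 to 0.46.

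Hepatocyte markers were scarce in both groups, and 0 of 22 reached 10 CPM in untreated cells. The identity of the cells was taken from the labels and was not verified, which limits what marker levels show. ALB, APOA2, APOB, TTR, FGA, FGB, FGG, FOXA2 and AFP had 0 counts in all 4 libraries, which allows up to 0.170 to 0.233 CPM, and 4 of 22 markers reached 1 CPM in untreated cells. SERPINA1, which encodes alpha-1 antitrypsin, fell from 5.99 to 1.35 CPM, and HNF4A, a hepatocyte transcription factor, had 49 and 65 counts in the untreated against 1 and 9 in the clofazimine libraries. Of 5 markers tested these 2 fell and 0 rose (2 adjusted over the list alone), and the list was not called (camera adjusted p 0.14).

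Some markers of other cell types were present, with 5 of 10 fibroblast, 4 of 10 endothelial and 2 of 10 leukocyte markers at 1 CPM or more in untreated cells. COL1A2, PDGFRA, POSTN, THY1, KDR and LYZ were at 0.114 CPM or less in both groups. Of 5 fibroblast markers tested, PDGFRB (-2.96), COL3A1 (-2.45), COL5A1 (-1.75) and DCN (-1.28) fell and COL1A1 (0.44) rose (5 changed adjusted over the list alone, camera adjusted p 0.022, and adjusted p = 0.46 with an estimated correlation). COL5A1 was at 1803 CPM in untreated and 537 CPM in clofazimine libraries. The call of the list ended with the length and GC correction (camera adjusted p 0.11, over a range from 0.013 to 0.46), at a median of -1.37 against -1.75 without it, with COL3A1 (-2.16) and COL5A1 (-1.24) still called. The COL1A1 call ended without untreated replicate 1 (0.43) or 2 (0.44) and under library totals (0.28, where 0 of the 5 markers were higher and 4 lower), and COL1A1 was at 0.92 with the length and GC correction. Of 4 endothelial markers tested 3 fell (3 adjusted over the list alone), namely ENG from 435 to 221 CPM, PECAM1 from 25.9 to 5.00 CPM and CDH5 from 2.92 to 0.874 CPM. The 3 leukocyte markers tested fell (3 adjusted over the list alone), among them CSF1R from 5.43 to 2.31 CPM and CD14 from 36.7 to 19.6 CPM, while PTPRC had 0 counts in all 4 libraries. The endothelial and leukocyte lists were too short for camera.

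Mesenchymal markers divided evenly, with 5 of 15 higher, 5 lower and 5 not called (10 changed adjusted over the list alone, camera adjusted p 0.21). SNAI2 and SNAI1, transcription factors of epithelial-mesenchymal transition, rose by 4.87 and 1.14, while the matrix genes SPARC and FN1 fell by 4.06 and 1.69 on the log2 scale. Among epithelial markers 5 of 12 were higher and 3 lower (8 changed adjusted over the list alone, camera adjusted p 0.62), with the tight junction genes CLDN1 and OCLN at 2.38 and 1.59 and E-cadherin (CDH1) at -1.52, and 4 each way under library totals. YAP/TEAD targets had 2 of 13 higher and 6 lower (8 changed adjusted over the list alone, camera adjusted p 0.12), with NT5E at -1.26 and TGFB2 at -1.20. Under library totals 0 of these were higher and 8 lower, and fry called the list (adjusted p 0.048). Wnt/beta-catenin targets had 3 of 15 higher and 5 lower (8 changed adjusted over the list alone, camera adjusted p 0.50), with AXIN2 at -3.29, DKK1 at -2.31 and TCF7L2 at 1.20, and 2 higher and 7 lower under library totals. Hypoxia and glycolysis genes had 5 of 22 higher and 8 lower (13 changed adjusted over the list alone, camera adjusted p 0.53), with VEGFA at 1.56 and EGLN3 at -2.35, and 3 higher and 11 lower under library totals.

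**Figure D3:**
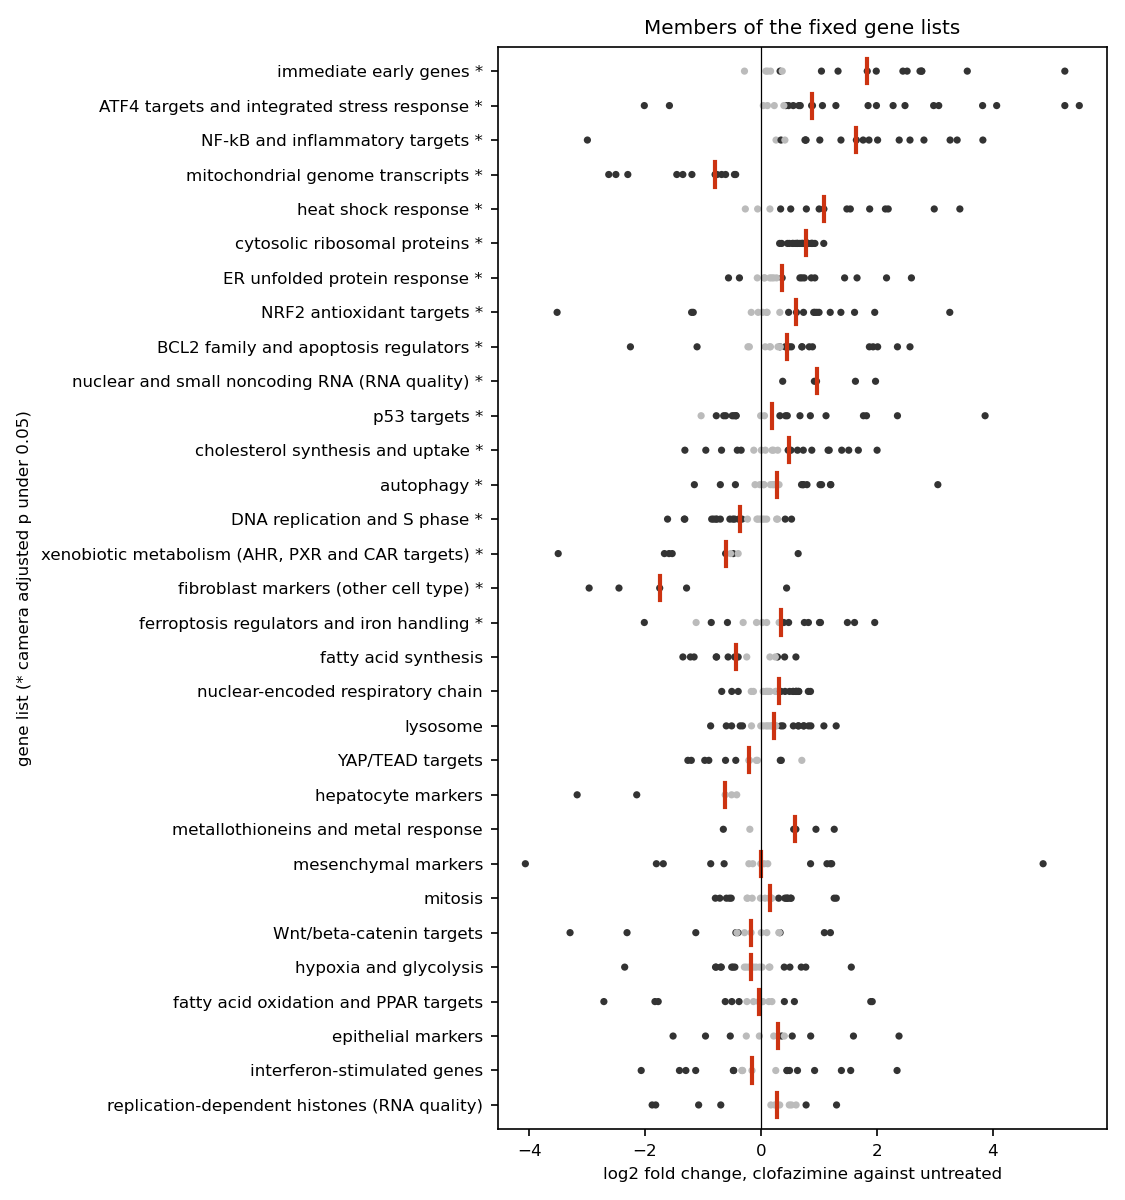
Log2 fold change of clofazimine against untreated for each tested member (points, dark where the adjusted p was under 0.05 and grey otherwise) of the 31 lists tested, with a red line at each list's median and a star at lists that camera called with the preset correlation. Immediate early genes lie highest (median 1.83), and the 13 mitochondrial protein-coding genes are all below 0 (median -0.79). With an estimated correlation, which leaves 2 residual degrees of freedom for the test, camera called 0 lists.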

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

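The correction for exon length and GC content was chosen after the data were seen. The other alternatives were planned. Under every alternative the counts of changed genes stayed within 1.5 times the main count of 9811, from 7420 without untreated replicate 2 to 9977 with library totals, and those of at least 2-fold changes lay between 3571 with DESeq2 and 4543 with library totals. Leaving out 1 library leaves its group with 1 sample, which is then assumed to vary like the other group. That gave 7420 to 9811 changed genes and 15 to 20 called lists. DESeq2 kept 8110 of the 9811 calls and the length and GC correction 8167, with 5 called in the opposite direction. The 32 genes taken by the naming rule kept direction and call in 384 of 384 gene and setting pairs. The 110 other genes checked in this way kept both in 1274 of 1319 pairs, and 13 of them lost a call in at least 1 setting.

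The result that moved was the count of called lists, which was 17 with the preset correlation and 0 with an estimated inter-gene correlation (camera, 2 lists at an unadjusted p under 0.05, against 23 called by fry). A fit with 2 libraries per group leaves 2 residual degrees of freedom. The estimate lay below the preset 0.01 for the called lists of immediate early genes (-0.046), mitochondrial mRNAs (-0.050) and nuclear and small noncoding RNAs (-0.18). It was also lower for autophagy (-0.015) and ferroptosis regulators (-0.011). Their calls ended all the same, which argues against a higher inter-gene correlation as the cause for these lists. The other called lists had estimates above 0.01, from 0.032 for p53 targets to 0.88 for cytosolic ribosomal proteins, with 0.67 for ATF4 targets. With an estimated correlation camera tests on the residual degrees of freedom, and with a preset one on a number set by the genes tested. For the lists with estimates below 0.01 the lost calls are therefore put down to the few degrees of freedom. For the other called lists the few degrees of freedom and a higher correlation cannot be told apart. Of 187 pairs of a called list and a setting 164 kept the call and 23 lost it, of 153 pairs of an uncalled list and a setting 13 gained a call, and 0 of the 340 changed direction with a call. Besides the estimated correlation, calls were lost for cholesterol synthesis, xenobiotic metabolism, fibroblast markers (camera adjusted p 0.11 with the length and GC correction, over a range from 0.013 to 0.46, at a median of -1.37 against -1.75) and ferroptosis regulators, and gained for fatty acid synthesis, the respiratory chain and the lysosome. Fry alone gave calls for YAP/TEAD targets (0.048), hepatocyte markers (0.023), metallothioneins (0.047), mesenchymal markers (0.042) and mitosis (0.016).

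Replicate numbers are shared between the groups, but the labels tie them to no shared culture or day, and same-numbered libraries did not deviate together (correlation -0.05). With the number as a replicate block 9605 genes changed, 9518 of them called without it, and 17 lists were called. The block ended the call of SNHG14 (-0.44, adjusted p 0.059) and no other call among the genes and lists checked.

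MT-RNR1 had the opposite sign with the length and GC correction (-0.058, adjusted p 0.69, with MT-RNR2 at 0.02), and the cause was not tested. The correction also ended the calls of CRELD2 (-0.28), SREBF2 (-0.01), ATG9A (-0.14), POLE2 (0.26), NPAS2 (-0.21) and SNHG14 (-0.12). It moved by over 1.5 times, with the call kept, XPC (to -0.42), DDB2 (-0.28), FDPS (-0.43), TP53INP2 (-0.44), STEAP3 (-0.57), LPCAT3 (-0.35), FASN (-0.34), SDHA (-0.39), CTSB (-0.54), PLK1 (-0.49), SMG6 (-0.37), MT-ND4 (-0.77), MT-ATP6 (-1.03), DNAJC3 (-0.61) and COL1A1 (0.92).

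Depth limits what can be said of genes at or under 3 counts, up to 0.233 CPM in the shallowest library.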

Other observations

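The families and lists set against random lists below, the host genes of small nucleolar RNAs included, were chosen after their values were seen, except the decay factors, which were listed after other data but before their own values were seen. Also chosen after were the tests of mitochondrial RNA yield, of the spread between mitochondrial mRNAs after correction, of genomic DNA, of unspliced RNA, of genomic span and of length trends within a group. The random lists were drawn gene by gene and do not carry the correlation between members of a family. A rank against them describes the size of a median and is not a test of it.

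Of 17 clock genes and output genes tested 12 were higher, 2 lower and 3 not called, at a median log2 fold change of 1.04, above the highest of 10000 random lists of matched expression (0.81). Beside NR1D1, its relative NR1D2 rose by 2.49, the transcription factor DBP by 2.55, the period gene PER1 by 2.35 and the repressor CIART by 3.50. The 2 lower genes encode partners of ARNTL, CLOCK (-0.76) and NPAS2 (-0.58), and the NPAS2 call ended with the length and GC correction (-0.21). Collagen genes moved the other way, with 21 of 26 lower and 2 higher at a median of -1.01, at percentile 0.01 of the random lists, which were matched on expression and not on length. With the length and GC correction 17 were lower and 2 higher, at a median of -0.71. The collagens share COL3A1 (-2.45), COL5A1 (-1.75) and COL1A1 (0.44) with the list of fibroblast markers, in which DCN (-1.28) and PDGFRB (-2.96) were also lower and whose call ended with that correction (camera adjusted p 0.11, over a range from 0.013 to 0.46) at a median of -1.37 against -1.75, with COL3A1 (-2.16) and COL5A1 (-1.24) still called.

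Mitochondrial ribosomal proteins had 44 of 78 higher and 2 lower (median 0.51, against 0.505 for the highest random list), and 38 higher and 8 lower under library totals (median 0.34, or 0.40 with the length and GC correction). Proteasome subunits had 23 of 38 higher and 2 lower (median 0.49, percentile 99.9), and 21 higher and 6 lower under library totals (median 0.32). Cytosolic aminoacyl-tRNA synthetases had 12 of 17 higher and 0 lower (median 0.61, percentile 98.1), led by GARS at 1.37 and SARS at 1.25. Solute carriers, the transporters of small molecules, had 103 of 240 lower and 42 higher (median -0.25, against -0.24 for the lowest random list). They had 124 lower and 27 higher under library totals (median -0.42), and 91 lower and 62 higher with the length and GC correction (median -0.17).

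The mRNAs of the 13 mitochondrial protein-coding genes, counted by gene, fell unequally. They ranged from -0.44 in MT-ATP6 to -2.63 in MT-ND6, and to -2.50 in MT-ND5 among the heavy-strand genes. Against a lower yield of all mitochondrial RNA, the 2 ribosomal RNAs stood above the median of the mRNAs by 1.15. The error set against this was 0.24, the SE of the ribosomal RNA mean plus the median SE of the mRNAs. It leaves out the spread between the mRNAs, whose SD was 0.78. For distance from the heavy-strand promoter, the fold change of the 12 heavy-strand mRNA genes followed their position with a Spearman rho of 0.00699 (permutation p 0.99, Pearson r -0.04, permutation p 0.90, both 0.99 after Benjamini-Hochberg adjustment over 2 tests). In 24 of 66 gene pairs the downstream gene was higher by over 2 SE, against 16 where it was lower. That argues against a steady fall with distance among these mRNA genes only. The test left out MT-RNR1 and MT-RNR2, which start at 648 and 1671, nearer the promoter, and stood at 0.35 and 0.36. With so few genes, distance over the whole strand is not excluded. With the length and GC correction the 13 genes were still lower, at a median of -1.65, and still unequal, with an SD of 0.851 against a median SE of 0.132. That argues against length and GC content as the whole cause of the fall or of the differences. A difference in synthesis or stability between mitochondrial transcripts under clofazimine may remain, as a hypothesis that these libraries cannot test.

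Of 23 host genes of small nucleolar RNAs tested, a class that shares the 5' terminal oligopyrimidine motif with ribosomal protein genes, 16 were higher, 6 not called and 1, SNHG14, lower (-0.43, a call that ended without any 1 of the 4 libraries, at -0.40 to -0.47, with the replicate block at -0.44, and also with DESeq2 or its size factors, without a filter and with the length and GC correction), at a median of 1.21 that exceeded the highest random list (0.75), with SNHG12 at 2.53, ZFAS1 at 2.33 and GAS5 at 1.98. Length and GC content as the whole cause were argued against by the correction, after which the median was 1.19. For genomic DNA no gain in detected genes was seen. At equal depth the clofazimine library with the most genes had fewer than the untreated library with the fewest (difference -1030 genes). Long intergenic noncoding RNAs, which genomic DNA was predicted to raise, did not rise as a group, with 114 of 664 higher and 255 lower (median -0.63, or -0.79 under library totals). Neither result can exclude genomic DNA, because genes that fell with clofazimine could hide such a gain in both. Unspliced RNA is a candidate explanation that stays open beside more transcription, since the 11 snoRNA genes and sense-intronic transcripts tested inside host and ribosomal protein genes were all higher (median 2.66), as were 34 of 38 snoRNA genes (median 2.37) and 88 of 184 sense-intronic transcripts, with 21 lower (median 0.87). With the length and GC correction these counts were weaker, at 19 of 38 snoRNA genes higher (median 1.14) and 54 sense-intronic transcripts higher and 32 lower (median 0.25). The correction was fitted on the tested genes with these short features among them, so it may have removed part of their own rise. Less nonsense-mediated decay, which degrades many host RNAs, would raise the decay factors that regulate themselves. Their median was 0.47 (0.30 under library totals, 4 of 7 higher, SMG6 lower at -0.84), above the level predicted before their values were seen. A further condition, on their rank among random lists, was not part of that prediction and was not met, at percentile 86.2. Less decay and a change in transcription cannot be told apart, because the factors moved both ways and their rank was not extreme.

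Longer transcripts were lower, with a median log2 fold change of 0.26 in the shortest and -0.27 in the longest of 10 equal groups of 12993 genes by exon length. GC content and genomic span did not account for it, as the coefficient of log2 exon length was -0.21 alone and -0.29 with GC content, and that of span was 0.0201 ± 0.0057 (SE). A trend in 1 library and one in both cannot be told apart, since the 4 single pairs had a Spearman rho from -0.0724 to -0.21, and the weakest was no stronger than that between the untreated libraries (-0.08). The clofazimine libraries, however, differed from each other with a rho of -0.35, more than the groups did (-0.15). A yield of long transcripts that varies between libraries is therefore a candidate explanation, and the trend between groups is not set apart from it.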
